A study of Geobacter sulfurreducens with 10 samples.

How the data were processed

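RNA from Geobacter sulfurreducens strain PCA was measured by RNA sequencing in 10 libraries that the labels place in 5 groups of 2. Per the labels' protocols, RNA was preserved in the culture before harvest, total RNA was extracted with a column kit and residual DNA was digested. Ribosomal RNA was reduced with an exonuclease that degrades RNA carrying a phosphate at its start. The fragmented RNA was copied with random hexamers, amplified by PCR and sequenced on an Illumina Genome Analyzer IIx. Strand use during counting, the genome build and the annotation are not given in the sources used here, so reads from overlapping or antisense genes cannot be told apart and no coordinates are given. Per the submitters' processing notes the tools were bcl2fastq, Bowtie2, bedtools and edgeR, without versions or settings.

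The authors deposited 4 tables, 1 per nitrate group against the control. Each holds raw read counts per gene for 4 libraries, which per the file headers and the values are whole numbers with no normalization. The deposited normalized signal columns were the counts times 1 factor per library, with a coefficient of variation of that factor of at most 1.89e-10 within a library, and were not used for tests. The deposited log2 fold changes, mean log2 CPM, p-values and adjusted p-values of the authors' own comparisons are per the file headers; the calls at an adjusted p under 0.05 were counted and are quoted as the authors' deposited table. The authors' test and design are not given in the sources used here.

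The 4 tables were joined by locus tag. The control counts were the same in all 4 tables, with 0 differing values. The tables listed only genes with counts in at least 2 of their 4 libraries, so 3184 of 3376 genes were in all 4 tables and 192 were absent from at least 1. Tests used the 3184 genes, and an alternative set the absent counts to 0. Of the locus tags, 3351 matched the RefSeq gene table of assembly ASM798v2, which was used for symbols, gene types and gene order only. A symbol was found for 781 genes, 670 of them in the tables themselves; no product names were used. Genes without a symbol are given by locus tag, and where such a gene had been entered beforehand under a name, that name is given as such.

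Groups were taken from the sample titles. The library titled acetate-nitrate 144 h, replicate 2, carries a treatment label of hydrogen-nitrate 144 h. It was kept with its title, and an alternative grouped it by the treatment label. The labels call each a biological sample without saying that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

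Differential expression was tested with edgeR 4.0.16 in R 4.3.3 by the two-sided quasi-likelihood test with TMM scaling and the edgeR expression filter at a minimum count of 10. All 10 libraries entered 1 fit of 5 groups with 5 residual degrees of freedom, with Benjamini-Hochberg adjustment at 0.05 and no fold minimum. The filter left 1823 genes, and the common dispersion was 0.213. The 4 nitrate groups were each compared with the control, the 2 times with each other within each electron donor, and the 2 donors with each other at each time; the interaction of donor and time was also tested. A comparison of all 8 nitrate libraries with the control was added after the similarity of the libraries had been seen. Normalized CPM values are counts scaled to the TMM-adjusted library size, given as mean ± SD with n = 2 per group. Errors of log2 fold changes are the absolute log2 fold change divided by the square root of the test's F statistic. They are approximate, above all for genes with few counts in a group.

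Named genes followed a rule fixed before the data were examined. In each comparison it took the 8 largest rises and the 8 largest falls among genes past the threshold with a mean log2 CPM of at least 5 and no overlap between the libraries of the 2 groups, then up to 2 called members per direction of each described gene list, and a panel of genes whatever their result. Genes chosen after their values were seen are named as such. For a gene with no count in a group, the fold is a lower bound against a floor of 3 counts over the libraries of that group; for 1 to 3 counts the ratio is given with its 95% counting interval. Intervals and floors cover counting error only. PCR reads without molecular identifiers are not independent molecules: genes with a count of 2 outnumbered genes with a count of 1 in all 10 libraries, 162 against 100 in control replicate 0, and 49.4% to 58.1% of gene counts from 1 to 40 were even. Whether both mates of a read pair were counted is not given in the sources used here; if so, floors and intervals rest on fewer fragments than counts, and the intervals are too narrow.

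Of 27 gene lists fixed before the data were examined, 10 had no member by symbol or locus tag, and 1 was the panel. The remaining lists were ribosomal proteins, acetate and tricarboxylic acid cycle enzymes, ATP synthase, NADH dehydrogenase, hydrogenases, c-type cytochromes, pili and nitrogen oxides. Others were nitrogen fixation, ammonium assimilation, amino acid biosynthesis, chaperones and proteases, cell division, CRISPR, iron uptake, and flagella and chemotaxis. The amino acid list was built on symbol patterns and also holds aminoacyl-tRNA synthetases such as serS and hisS. The cell division list also holds ftsY and the protease genes ftsH (GSU1180 and GSU1809), which are in the protease list too. Lists with at least 3 tested members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with the correlation estimated from the data and with fry as alternatives, adjusted over lists within a comparison.

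Libraries were compared in pairs by the chi-square of their counts per degree of freedom and by Pearson's r of log2 CPM across genes, which are not independent replicates. Both were repeated after each library was thinned to 44410 protein-coding counts, with GSU3409 and GSU3410 left out. The control libraries alone were also thinned, to 93127 protein-coding counts. Overlaps between comparisons with the same controls were set against 20 simulations of unchanged groups. The alternatives were RLE size factors, no filter, DESeq2 1.42.0, a fold minimum of 2, a fit of only the 2 groups compared, the replicate number as a block, and leaving out each library in turn. Scaling to total counts, scaling to protein-coding counts, absent genes at 0 and the nitrate libraries alone were chosen after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for joins and figures.

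The tests were checked on simulated counts with 100 genes changed 4-fold and 100 changed 16-fold among 1823. In the 4 comparisons with the control, 31%, 31%, 31% and 28% of the 4-fold changes were recovered at hydrogen-nitrate 48 h and 144 h and acetate-nitrate 48 h and 144 h, and 87%, 83%, 89% and 75% of the 16-fold changes. Between 4 and 7 unchanged genes were called in these 4 simulations. TMM factors were 2.72 and 2.61 in the control libraries and 0.595 to 1.2 in the nitrate libraries. The median log2 fold change over all tested genes was −0.16, −0.13, −0.12 and −0.26 in the same order with TMM; scaling to total counts moved it to −2.08, −1.57, −1.76 and −2.14, and scaling to protein-coding counts to −1.29, −0.90, −1.14 and −1.61. All fold changes are relative to the TMM scale.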

Results

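Gene counts were available for 10 libraries of Geobacter sulfurreducens PCA, a bacterium that respires by passing electrons to fumarate, metals and other acceptors. The control group was harvested in exponential growth in NBAF, a medium with acetate as electron donor and fumarate as acceptor. The other 4 groups were incubated with nitrate as acceptor and either hydrogen or acetate as donor, for 48 h or 144 h, with 2 libraries per group. These groups thus differ from the control in acceptor and in incubation before harvest, and the hydrogen groups in donor as well. Differences from the control therefore cannot be assigned to nitrate alone. Total counts were 282878 and 325466 in the control libraries and 146844 to 271499 in the 8 nitrate libraries. The median gene had 18 and 20 counts in the control libraries and 2 to 4 in the nitrate libraries.

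A few RNAs took most counts of the nitrate libraries. The transfer-messenger RNA ssrA, which frees stalled ribosomes, took 16.9% (95% Wilson interval 16.7 to 17.0) and 20.2% (20.1 to 20.4) of counts in the control libraries and 28.0% to 38.1% in the nitrate libraries. The RNA subunit of RNase P, rnpB, which matures transfer RNAs, took 7.55% ± 0.0803 (SD, n = 2) in the control and 14.9% to 17.5% in the nitrate libraries. Transfer RNA genes took 0.171% and 0.225% in the control and 0.0364% to 0.145% in the nitrate libraries. The 6S RNA gene ssrS took 0.202% and 0.284% in the control, within the 0.167% to 0.5595% of the nitrate libraries. The gene GSU3410 took 1.60% ± 0.0198 (SD, n = 2) in the control and 7.70% to 20.2% with nitrate. Protein-coding genes together held 72.4% ± 2.46 (SD, n = 2) of control counts and 44.96% to 55.4% of nitrate counts.

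**Figure D1:**
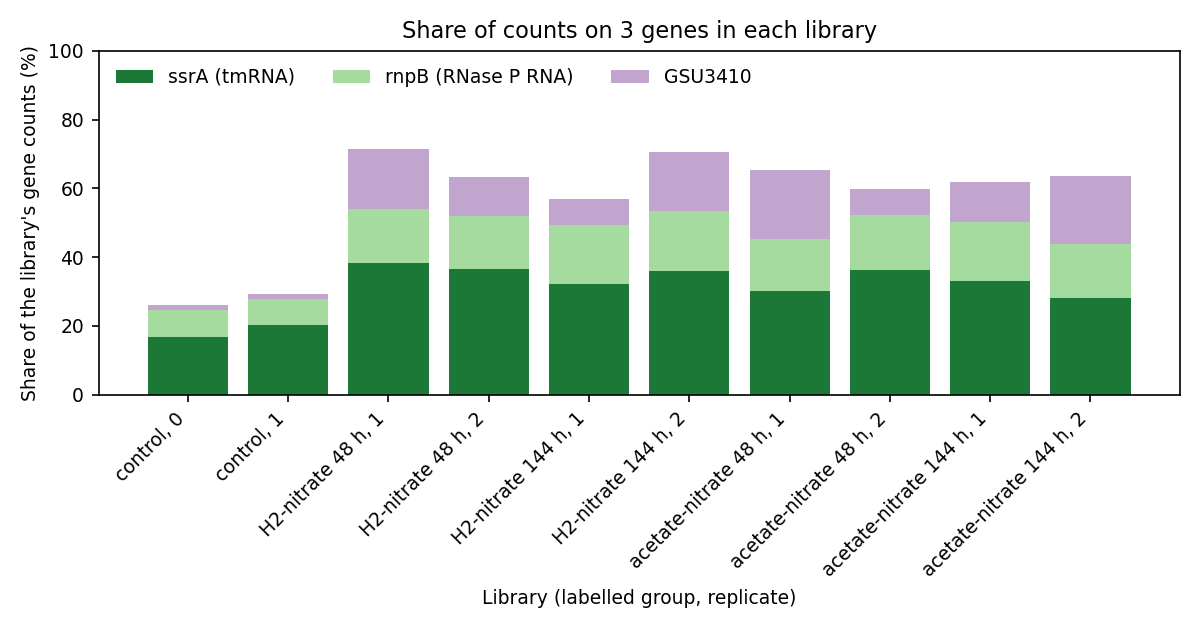
Stacked bars give the percentage of each library's gene counts that fell on ssrA, rnpB and GSU3410, with 1 bar per library, labelled by group and replicate. ssrA ranged from 28.0% to 38.1% in the 8 nitrate libraries, above the 16.9% and 20.2% of the control libraries.

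The nitrate libraries did not resemble their labelled replicates most. Each of the 8 was closest to a library of another labelled group, and these libraries formed 4 mutual pairs. Hydrogen 48 h replicate 1 paired with hydrogen 144 h replicate 2, and hydrogen 48 h replicate 2 with acetate 144 h replicate 1. Hydrogen 144 h replicate 1 paired with acetate 48 h replicate 2, and acetate 48 h replicate 1 with acetate 144 h replicate 2. The chi-square per degree of freedom was 2.39 to 2.88 within these pairs and 2.61 between the control libraries, against 16.04 to 32.7 between labelled nitrate replicates. After thinning to 1 protein-coding total without GSU3409 and GSU3410 it was 1.99 to 2.08 within the pairs and 6.12 to 19.97 between labelled replicates. The control pair, at 1.22, is not comparable with these because the control libraries lost a larger part of their counts. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.811 to 0.884 within the pairs, 0.965 between the controls and 0.705 to 0.806 between labelled replicates. Among the 105 ways to pair the 8 libraries, the labelled pairing ranked 75 by mean correlation. Reads are not independent molecules, and the control pair lay above 1 as well, so these values do not decide whether libraries of a pair are copies. Each library was counted as a separate sample. All comparisons below keep the groups as labelled, and every group mean of a nitrate group therefore averages libraries that differed in this way.

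**Figure D2:**
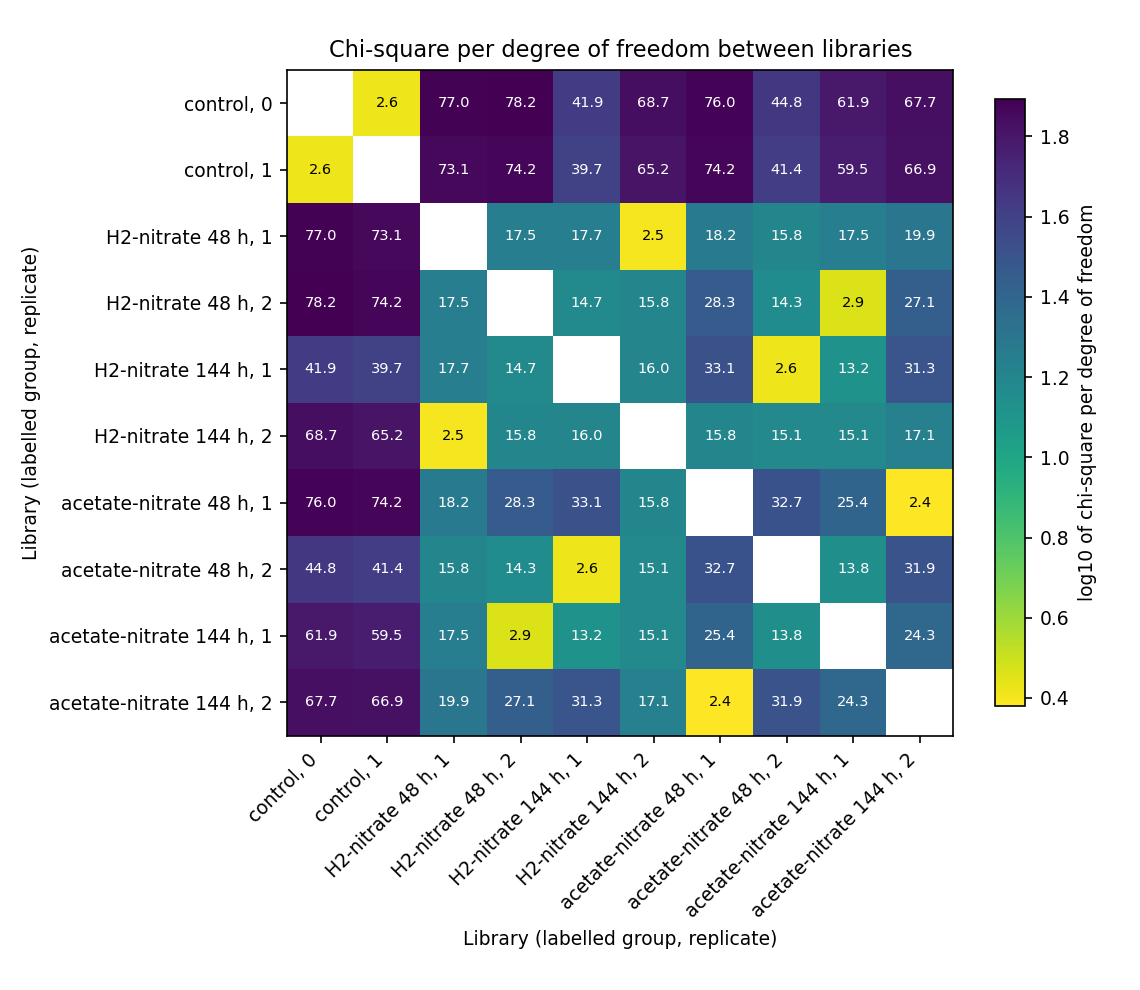
The heat map shows the chi-square per degree of freedom between the gene counts of each pair of the 10 libraries, printed in each cell and coloured on a log10 scale, with both axes labelled by group and replicate. The lowest values among nitrate libraries, 2.39 to 2.88, lie between libraries of different labelled groups.

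The comparison of hydrogen-nitrate at 48 h with the control asked which transcripts differ between cells incubated with hydrogen and nitrate and cells growing on fumarate. The sensor kinase gene gnfK (GSU0941), part of the system that controls nitrogen fixation genes in Geobacter, had 451 ± 443 normalized CPM (SD, n = 2) against 0.588 ± 0.831 in the control, a ratio of 759 with a counting interval of 134 to 30100 on 1 control count. Its partner regulator gene gnfR (GSU2822) was at least 36.8-fold higher, and the glutamate dehydrogenase gene gdhA (GSU1305) at least 64.4-fold higher, each with no control count. GSU3154, entered in the list beforehand as the nitrite reductase nrfA, was at least 38.3-fold higher, with counts of 1 and 24 in the nitrate libraries and 0 in the controls. The glutamine synthetase gene glnA rose by a log2 fold change of 3.30 ± 0.91 (adjusted p = 0.0356). nifU, an iron-sulfur scaffold, rose by 2.37 ± 0.64 (adjusted p = 0.0329) and GSU0618, entered beforehand as the cytochrome omcE, by 2.40 ± 0.71 (adjusted p = 0.0433). Other large rises were GSU0172, with a log2 fold change of 7.29 ± 0.98, GSU0967 with 6.82 ± 1.66 and GSU0936, at least 36.8-fold higher. GSU0224 had a ratio of 365 with a counting interval of 99.5 to 3040. GSU0967 had 10 and 289 counts in the nitrate libraries, and without replicate 2 its log2 fold change was 3.07 and that of glnA 1.30, with GSU0967, glnA and GSU3154 no longer called.

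In the same comparison, of 48 ribosomal protein genes tested, 9 were lower and 0 higher, with 18 lower when adjusted over the list alone. The median log2 fold change was −1.96, or −1.89 with genes without counts set at their bound. rpsC was at least 11.6-fold lower and rplP at least 4.5-fold lower. Of 18 genes of acetate use and the tricarboxylic acid cycle, 7 were lower and 0 higher, with 11 lower when adjusted over the list alone and a median of −2.18, among them sucC, a succinyl-CoA ligase subunit, at −3.29 ± 0.72 (adjusted p = 0.0129). By camera the ribosomal list had an adjusted p of 3.39e-08 and the acetate list of 4.03e-05; the adjusted p was 0.109 for both with an estimated correlation. The elongation factor gene efp had a ratio of 65.5 in favour of the control (counting interval 18 to 542), and GSU0013 had a log2 fold change of −6.20 ± 1.01. GSU3530 had a ratio of 98.5 (27.2 to 815) and GSU1409 of 65 (11.6 to 2580) in the same direction. GSU0011, GSU1651 and GSU2564 were at least 13.4-fold, 12.2-fold and 4.13-fold lower. Single members of other lists fell as well, such as the ATP synthase subunit gene atpA at −4.04 ± 0.83 and the division genes ftsZ at −2.73 ± 0.83 and ftsL at −2.94 ± 0.87. The protease gene ftsH at GSU1809 was at −2.15 ± 0.62, while the second ftsH, GSU1180, was at −1.35 and not called. nifJ, a pyruvate oxidoreductase, was at −2.63 ± 0.75, and GSU0785, entered beforehand as the hydrogenase subunit hybL, at −2.46 ± 0.73. The pilus secretin gene pilQ rose by 2.12 ± 0.64 (adjusted p = 0.044), and aroF at GSU3142, the entry enzyme of aromatic amino acid synthesis, was lower at −2.29 ± 0.61. A second aroF, GSU3333, was at −0.68 here. It was at −1.47, −0.85 and −1.02 at hydrogen 144 h, acetate 48 h and acetate 144 h, called in none. All later values of aroF are for GSU3142.

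In total 117 genes were higher and 114 lower at hydrogen-nitrate 48 h by edgeR, and 573 had an unadjusted p under 0.05; the authors' deposited table has 200 higher and 384 lower. The split was 92 and 152 with RLE size factors, 33 and 822 with scaling to total counts, and 40 and 369 with scaling to protein-coding counts, and the rises of glnA, nifU, GSU0618 and pilQ were no longer called with either of the last 2 scalings. Without control replicate 0 or 1, 8 and 7 genes were called, and without nitrate replicate 1 or 2, 141 and 20. Of 30 named calls, 25 ended without 1 or the other control library, and 11 and 25 without nitrate replicate 1 and 2. The fold change moved by over 1.5 times in 1 and 3 without control replicate 0 and 1, and in 14 without 1 or the other nitrate library. A fit of only these 2 groups called 388.

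At hydrogen-nitrate 144 h, GSU0172 and GSU0186 rose to 1989 ± 203 and 5474 ± 905 normalized CPM (SD, n = 2) against 8.41 ± 6.39 and 130.8 ± 1.24 in the control, log2 fold changes of 7.80 ± 0.996 and 5.38 ± 0.80 (adjusted p = 0.00243 and 0.0034). GSU3478 rose by 6.13 ± 0.82 (adjusted p = 0.00243). gnfK had a ratio of 155 with a counting interval of 25.9 to 6320, GSU0224 of 165 (43.9 to 1390) and GSU1239 of 105 (16.9 to 4350). gdhA was at least 41.7-fold and GSU0936 at least 28.4-fold higher. GSU3154 had counts of 2 and 2 and no control count, a bound of 6.67-fold, and was not called (adjusted p = 0.142). hcp, the hybrid cluster protein linked to nitric oxide and hydroxylamine, was not called either (log2 fold change 1.95 ± 1.18, adjusted p = 0.296).

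At hydrogen-nitrate 144 h ribosomal protein genes had 5 of 48 lower and 0 higher, 11 lower when adjusted over the list alone, with a median of −1.76. rplT was at −4.22 ± 0.89, and rpmD had a ratio of 17.4 in favour of the control (3.04 to 694). Acetate and tricarboxylic acid cycle genes had 6 of 18 lower and 0 higher, 12 lower when adjusted over the list alone, with a median of −2.08. sucC was at −3.09 ± 0.71 and GSU1178 at −3.53 ± 1.03. camera gave adjusted p = 3.16e-07 and 0.00013 for these lists, and adjusted p = 0.135 for both with an estimated correlation. The ATP synthase subunit gene atpE was at least 7.73-fold lower, and the cell wall gene murA had a ratio of 43.8 in favour of the control (7.77 to 1740). The protease gene ftsH at GSU1809 was at −3.14 ± 0.67, while the ftsH at GSU1180 was at −1.26 and not called. GSU1496, entered beforehand as the pilin pilA, was at −3.36 ± 0.84 (adjusted p = 0.0279). serS, a tRNA synthetase, was at −1.98 ± 0.58 and aroF at −2.36 ± 0.62. GSU2587 had a ratio of 128 (23 to 5080), GSU1018 of 89.9 (16.1 to 3560), GSU3530 of 60.3 (20.6 to 293) in favour of the control. GSU1409 had a ratio of 59.7 (10.6 to 2370) and GSU1408 of 37.5 (12.8 to 182) in the same direction, and GSU1406 was at least 9.66-fold lower.

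The test called 72 genes higher and 85 lower at hydrogen-nitrate 144 h, with 522 at an unadjusted p under 0.05, and the authors' deposited table has 197 higher and 422 lower. RLE size factors gave 60 and 114, scaling to total counts 26 and 520, and scaling to protein-coding counts 26 and 205. Without control replicate 0 or 1 the test called 0 and 3 genes, without nitrate replicate 1 or 2 it called 15 and 9, and a fit of only these 2 groups called 504. Of 24 named calls, 24 and 21 ended without control replicate 0 and 1, and 18 and 20 without nitrate replicate 1 and 2, that of GSU0936 among the last. The fold change moved by over 1.5 times in 3 without 1 or the other control library, and in 10 and 9 without nitrate replicate 1 and 2. With the acetate 144 h library of conflicting labels added to this group, 100 genes were higher and 118 lower, and GSU1496, rpmD and murA were no longer called.

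At acetate-nitrate 48 h the largest rises included a run of neighbouring genes. GSU0224 had 2204 ± 2880 normalized CPM (SD, n = 2) against 1.24 ± 0.0873 in the control, a ratio of 1400 with a counting interval of 386 to 11600. GSU0223 rose by a log2 fold change of 7.81 ± 1.53 (adjusted p = 0.00796), and GSU3479 was at least 75.6-fold higher. The libraries differed: GSU0224 had 465 counts in replicate 1 and 30 in replicate 2. GSU3247 and GSU3248 rose by 7.87 ± 1.73 and 7.63 ± 1.41, GSU0172 by 8.27 ± 1.01, and gdhA was at least 132-fold higher. In the nitrogen oxide list, hcp rose by 5.55 ± 1.36 (adjusted p = 0.0216) with 582 and 52 counts, and GSU3154 was at least 43.5-fold higher with 21 and 2 counts. The ferrous iron transporter gene feoB at GSU3268 rose by 2.53 ± 0.65 and nifU by 2.36 ± 0.64. A second feoB, GSU1380, was at −0.19 here and 0.26 at acetate-nitrate 144 h, called in neither. The hydrogenase-type membrane gene hybB at GSU0779, near the formate dehydrogenase gene fdnG, rose by 3.02 ± 0.85.

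Among the genes that fell at acetate-nitrate 48 h, the dihydrolipoyl dehydrogenase gene lpdA was at −5.08 ± 0.96 (adjusted p = 0.00597) and the malate dehydrogenase gene mdh at −3.69 ± 0.69 (adjusted p = 0.00597). Acetate and tricarboxylic acid cycle genes had 7 of 18 lower and 0 higher, 11 lower when adjusted over the list alone, with a median of −2.40, or −2.23 with genes without counts at their bound. GSU1070, acnB and GSU2707 had positive values of 2.17, 1.69 and 0.73 and were not called. GSU1470 had a ratio of 19.1 in favour of the control (3.35 to 759). For ribosomal proteins 1 of 48 was lower, rplF, with a ratio of 9.61 (2.6 to 80.4), none when adjusted over the list alone, and the median was −1.08. camera gave adjusted p = 0.00019 for the acetate list and 0.00369 for the ribosomal list, and adjusted p = 0.255 and 0.41 with an estimated correlation. The lipopolysaccharide transport gene lptA was at −4.34 ± 0.69, the leucine synthesis gene leuB at −3.06 ± 0.85, aroF at −3.27 ± 0.66, nifJ at −2.58 ± 0.75 and GSU0785 at −2.72 ± 0.74. Falls without a known symbol were GSU0013 at −5.40 ± 0.97, GSU3530 at −4.76 ± 0.80, and GSU2587 at −4.54 ± 0.82. GSU1651 had a ratio of 29.6 (5.25 to 1180) and GSU2970 of 26.6 (4.71 to 1060) in favour of the control, and GSU2354 was at least 8.47-fold lower.

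Altogether 110 genes were higher and 70 lower at acetate-nitrate 48 h, with 492 at an unadjusted p under 0.05, and the authors' deposited table has 137 higher and 262 lower. The split was 100 and 100 with RLE size factors, 42 and 598 with scaling to total counts and 47 and 239 with scaling to protein-coding counts, and the rises of nifU, feoB and hybB were no longer called with either of the last 2. Without control replicate 0 or 1, 0 genes and 1 gene were called, without nitrate replicate 1 or 2, 77 and 167. Of 27 named calls, 27 and 26 ended without control replicate 0 and 1, and 14 and 7 without nitrate replicate 1 and 2. The fold change moved by over 1.5 times in 2 without 1 or the other control library, and in 14 and 18 without nitrate replicate 1 and 2. Without replicate 1 the log2 fold changes of hcp and GSU3247 were 2.27 and 2.79, and hcp, GSU3247, GSU3154 and GSU3479 were no longer called. With only these 2 groups in the fit 116 genes were called, without hcp, GSU0223, GSU3247, nifU and GSU0785.

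At acetate-nitrate 144 h GSU0224 had 2732 ± 2510 normalized CPM (SD, n = 2), a ratio of 1980 to the control with a counting interval of 545 to 16400, and GSU0223 rose by a log2 fold change of 8.48 ± 1.57 (adjusted p = 0.00591), while GSU3479 was at least 132-fold higher. gnfK had a ratio of 855 (151 to 34000), gnfR was at least 60.6-fold, gdhA at least 80.8-fold and GSU3154 at least 85.3-fold higher, the last with 15 and 23 counts. hcp rose by 5.63 ± 1.36 (adjusted p = 0.0161) and glnA by 3.67 ± 0.93 (adjusted p = 0.0196). The feoB at GSU3268 rose by 2.45 ± 0.66, nifU by 2.45 ± 0.64, and GSU3247 by 8.05 ± 1.74.

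Acetate and tricarboxylic acid cycle genes had 9 of 18 lower and 0 higher at acetate-nitrate 144 h, 12 lower when adjusted over the list alone, with a median of −2.49. sucD, the other succinyl-CoA ligase subunit, was at −4.01 ± 0.79 (adjusted p = 0.00688), and GSU1470 had a ratio of 16 in favour of the control (2.82 to 639). Ribosomal proteins had 3 of 48 lower and 0 higher, 2 lower when adjusted over the list alone, with a median of −1.03. rplQ was at least 7.77-fold lower and rplR had a ratio of 14.7 (2.58 to 586). Of 7 genes in the cell division list 1 was lower, ftsA at −2.74 ± 0.66, and 5 when adjusted over the list alone. The median was −2.10, or −1.98 with genes without counts at their bound. That list includes ftsY and the ftsH protease genes, so its values are not those of division genes alone. The ftsH genes were at −2.10 and −1.98. ftsY had no count in the nitrate libraries of this group, so its fitted −5.90 is not a measured size. camera gave adjusted p = 0.000919, 0.00381 and 0.0288 for these lists, and adjusted p = 0.248, 0.352 and 0.248 with an estimated correlation. The hydrogenase genes hybB at GSU0784 and GSU0785 were at −3.32 ± 0.90 and −3.40 ± 0.77, atpA at −2.64 ± 0.77, the arginine synthesis gene argJ at −3.27 ± 0.94, aroF at −2.98 ± 0.65 and nifJ at −2.35 ± 0.74. GSU1408, GSU1409, GSU0670, GSU2831, GSU0011, GSU2295 and GSU1651 had no count in either nitrate library and were at least 27.9-fold, 14.8-fold, 12.8-fold, 10.3-fold, 9.16-fold, 8.91-fold and 8.32-fold lower.

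The test called 146 genes higher and 106 lower at acetate-nitrate 144 h, with 560 at an unadjusted p under 0.05, and the authors' deposited table has 197 higher and 390 lower. Scaling to total counts gave 47 and 813 and scaling to protein-coding counts 57 and 457, both without the rises of nifU, feoB and glnA. Grouping replicate 2 by its treatment label ended the calls of gdhA, hcp, glnA and GSU3154, but it left 1 library in this group. That library is then assumed to vary like the other groups. Without control replicate 0 or 1, 9 and 14 genes were called, without nitrate replicate 1 or 2, 116 and 157, and a fit of only these 2 groups called 433. Of 30 named calls, 27 and 25 ended without control replicate 0 and 1, and 13 and 12 without nitrate replicate 1 and 2. The fold change moved by over 1.5 times in 1 without 1 or the other control library, and in 16 and 12 without nitrate replicate 1 and 2. hcp had 130 and 501 counts in the nitrate libraries, GSU3247 78 and 462, GSU3479 6 and 53 and gdhA 4 and 32. Without replicate 2, hcp was at 3.94 and no longer called, while GSU3247, at 5.83, GSU3479 and gdhA were still called.

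**Figure D3:**
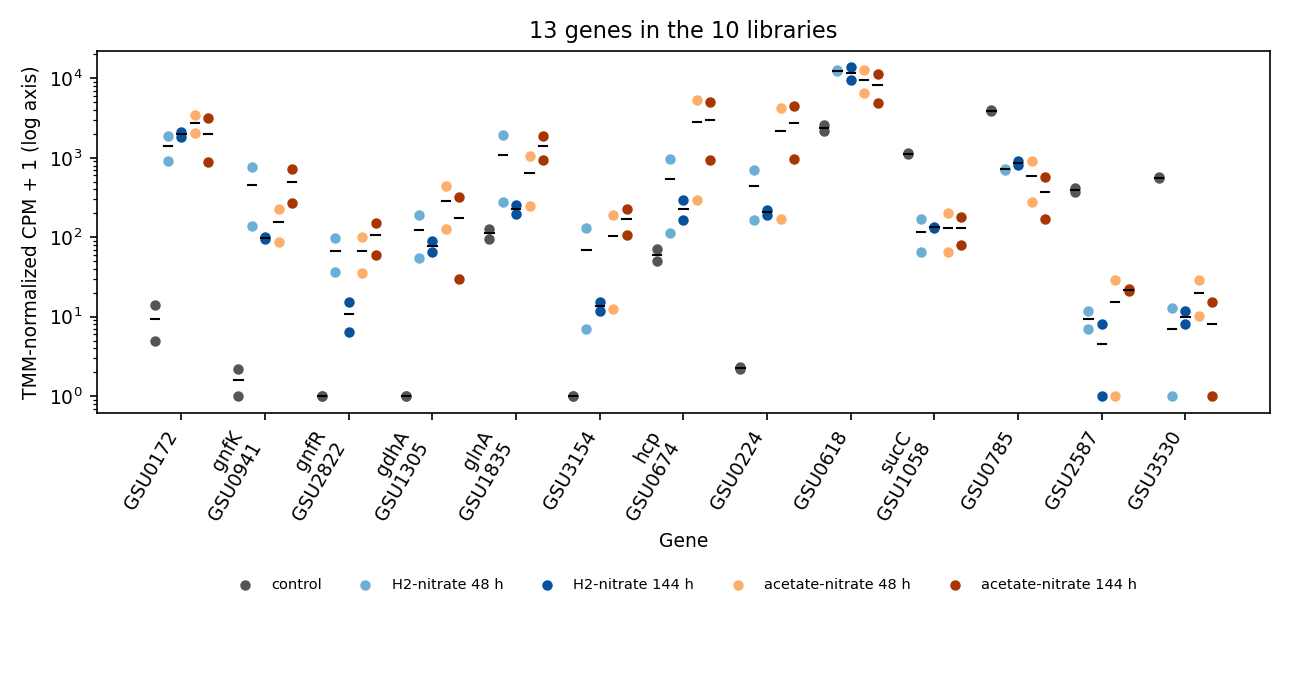
Points give the normalized CPM plus 1 of 13 genes in each of the 10 libraries on a log axis, coloured by labelled group, and short lines give the group means. GSU0172 lay between 892 and 3481 in the 8 nitrate libraries against 3.90 and 12.9 in the control libraries, and GSU3530 between 0 and 28.4 against 568 and 551.

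The 4 comparisons shared many genes. Higher in all 4 were 46 genes and lower in all 4 were 34, and no gene was higher in 1 and lower in another. Pairs of comparisons shared 56 to 96 higher genes, where independent lists would share 4.34 to 9.37, and 40 to 68 lower genes, where independent lists would share 3.26 to 6.63. Simulated unchanged groups had 0 calls in each comparison, so the 0 calls they shared say nothing about the effect of the shared controls on this overlap. The covariance of the log2 fold changes was 2.66 to 3.33, against 0.237 to 0.241 in simulations with the same controls, and the correlation across genes was 0.736 to 0.813 against 0.339 to 0.382. The covariance left after subtracting the simulated one was 2.43 to 3.09. The simulated groups shared only the controls, while the mutual library pairs joined libraries of different nitrate groups. The covariance left and the overlap of calls may therefore also hold the similarity within those pairs. The controls were not split because each part would hold 1 library, and how much of the overlap of calls came from them is not known.

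Some genes of the panel stayed on the same side of the threshold throughout. GSU1106, entered beforehand as the citrate synthase gltA, had log2 fold changes of −1.69 to −1.12 over the 4 comparisons and was not called. GSU0274, entered as the inner membrane cytochrome cbcL, had 1 count at hydrogen 48 h, a ratio of 8.48 in favour of the control (1.44 to 344). Its ratios at acetate 48 h and 144 h were 2.29 (0.729 to 11.6) and 1.93 (0.614 to 9.76) in the same direction, its log2 fold change at hydrogen 144 h was −0.15, and it was not called in any. Not called either were GSU2076, entered as the cytochrome omcZ, at −0.63 to 0.15, and GSU0612, entered as the periplasmic cytochrome ppcA, at −2.05 to −1.12. The same holds for GSU1024, entered as ppcD, at 0.86 to 1.71, GSU3259, entered as the inner membrane cytochrome imcH, at 0.45 to 1.17 and GSU0357 at −0.54 to 0.30. nrfD had no count at acetate 48 h, at least 2.59-fold lower (adjusted p = 0.083), and −0.44 to 0.82 in the other comparisons. The outer membrane cytochrome gene omcC lay at −0.16 to 0.50; omcB had no count at acetate 48 h, at least 2.59-fold lower (adjusted p = 0.092), and lay at −1.21 to 0.18 in the others. Read sharing between these related genes was not tested, so both values are uncertain. GSU1496 was called lower in 1 comparison, GSU0618 higher in 1, glnA and hcp higher in 2, GSU3154 higher in 3 and GSU0785 lower in 3; whether these differ between comparisons is given by the tests between nitrate groups. Of the panel and nitrogen oxide genes, 5 were not tested. nrfH was left out because only 2 tables list it, with 0 counts in the control and 25 in the nitrate libraries of those tables. The others had too few counts: omcS 14 in the control and 29 in the nitrate libraries, nifH 9 and 2, GSU1525, entered as the sigma factor rpoS, 19 and 6, and GSU3364, entered as the regulator hgtR, 1 and 20.

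The other gene lists did not pass camera in any comparison with the control, apart from cell division at acetate 144 h, given above. This depended on the method. With fry, ATP synthase and CRISPR (adjusted p = 0.0184 for both) and cell division (0.00176) passed at hydrogen 48 h, among other comparisons. Amino acid genes (0.0158), hydrogenases (0.0393) and pili (0.0389) passed fry at acetate 144 h. Cytochromes, NADH dehydrogenase, nitrogen fixation, nitrogen oxides, and chaperones and proteases passed fry in no comparison with the control. Hydrogenases had 1, 0, 1 and 3 of 13 genes lower and 0, 0, 1 and 0 higher at hydrogen 48 h and 144 h and acetate 48 h and 144 h, with 0, 0, 2 and 4 lower and 0, 0, 1 and 0 higher when adjusted over the list alone and a lowest adjusted p of 0.113. ATP synthase had 1, 1, 0 and 1 of 5 lower, 2, 1, 0 and 1 when adjusted over the list alone, lowest adjusted p = 0.0959. Nitrogen oxide genes had 1, 0, 2 and 2 of 4 higher, 2, 0, 2 and 2 when adjusted over the list alone, which also calls nrfD lower at acetate 48 h; lowest adjusted p = 0.151. Nitrogen fixation had nifU higher and nifJ lower in 3 of the 4 comparisons and neither called at hydrogen 144 h, both called in all 4 when adjusted over the list alone, lowest adjusted p = 0.511. Amino acid genes had 1, 2, 2 and 3 of 37 lower, 0, 0, 1 and 3 when adjusted over the list alone, lowest adjusted p = 0.342. Chaperones and proteases had 1, 1, 0 and 0 of 14 lower, the same numbers when adjusted over the list alone, lowest adjusted p = 0.656, and at acetate 48 h the list's median was −0.01 while its mean, 0.02, and camera's direction were positive. Of 6 pilus genes 1 was higher at hydrogen 48 h and 1 lower at hydrogen 144 h, with 1 higher and 2 lower, 2 lower, 0 and 1 lower when adjusted over the list alone, lowest adjusted p = 0.57. Cell division at hydrogen 48 h, hydrogen 144 h and acetate 48 h had 3, 1 and 0 of 7 lower, the same when adjusted over the list alone, with adjusted p of 0.112, 0.229 and 0.475. Of 11 c-type cytochrome genes 1 was higher at hydrogen 48 h, also when adjusted over the list alone, lowest adjusted p = 0.462; at hydrogen 48 h and acetate 48 h the list's median (0.50 and 0.15) and camera's direction were positive and its mean (−0.09 and −0.25) negative. The 10 NADH dehydrogenase genes and 4 CRISPR genes had no call, with lowest adjusted p of 0.402 and 0.352. Ammonium assimilation and iron uptake had 2 tested genes each and flagella and chemotaxis 1, too few for a test. The called members were glnA and the feoB at GSU3268, while the feoB at GSU1380 was not called.

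All 8 nitrate libraries were also compared with the control as 1 group, a comparison that does not depend on which nitrate group each library was labelled with. The 8 libraries formed 4 close pairs, which the fit, the SDs and the p-values do not take into account. Acetate and tricarboxylic acid cycle genes were lower in 13 of 18, and in 13 when adjusted over the list alone, with a median of −2.39. The camera adjusted p was 2.3e-05, and adjusted p = 0.0413 with an estimated correlation. sucC had 127 ± 53.2 normalized CPM (SD, n = 8) against 1132 ± 14.3 (SD, n = 2), a log2 fold change of −3.15 ± 0.41 (adjusted p = 5.54e-05), and lay below both controls in 8 of 8 libraries. Ribosomal protein genes were lower in 22 of 48, also when adjusted over the list alone, with a median of −1.40 and a camera adjusted p of 1.61e-05; the adjusted p was 0.237 with an estimated correlation. ATP synthase genes were lower in 4 of 5, also when adjusted over the list alone (camera adjusted p = 0.117). Of 13 hydrogenase genes 5 were lower and 1 higher, with the same counts when adjusted over the list alone (adjusted p = 0.168). GSU0172 rose by 7.84 ± 0.92 (adjusted p = 2.79e-05), gdhA was at least 77.7-fold, gnfR at least 31.9-fold and GSU3154 at least 40.4-fold higher, and gnfK had a ratio of 489 (87.2 to 19400). All 5 lay above both controls in 8 of 8 libraries. GSU3530 was at −5.65 ± 0.50 (adjusted p = 2.56e-06) and GSU0013 at −5.71 ± 0.56 (adjusted p = 6.95e-06), below both controls in 8 of 8. The rule for naming the largest rises and falls requires this lack of overlap, so it is no added evidence for these genes. By edgeR 217 genes were higher and 279 lower, with 715 at an unadjusted p under 0.05; scaling to total counts gave 53 and 1106 and scaling to protein-coding counts 74 and 652. clpB, trpD and GSU1024 were higher with TMM and at negative log2 fold changes with total counts. Without control replicate 0 or 1, 111 and 105 genes were called, and 30 and 29 of 51 named calls ended.

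The comparisons between nitrate groups asked how time and electron donor change transcripts, and no gene passed the threshold in any of them with edgeR after the count filter. Labelled replicates differed by a chi-square per degree of freedom of 16.04 to 32.7, against 2.39 to 2.88 within the mutual pairs. These tests take their spread from the labelled replicates, so the lack of calls does not show that time or donor had no effect. hcp had 5304 and 295 normalized CPM in the libraries labelled acetate 48 h and 928 and 4985 at acetate 144 h. Its values were 114 and 970 at hydrogen 48 h, and 296 and 163 at hydrogen 144 h. The cytochrome oxidase subunit gene coxB (GSU0222), chosen after its values were seen, had 7400 and 238 at acetate 48 h and 2533 and 7682 at acetate 144 h. It had 198 and 2494 at hydrogen 48 h and 235 and 184 at hydrogen 144 h. glnA had 1057 and 244, 1884 and 945, 276 and 1912, and 197 and 255 in the same order.

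Between 144 h and 48 h with hydrogen 0 genes were called, with a lowest adjusted p of 0.998 and 62 genes at an unadjusted p under 0.05, and with acetate 0, with a lowest adjusted p of 1 and 81 genes; DESeq2 called 0 in both. Between acetate and hydrogen at 48 h edgeR called 0 (lowest adjusted p = 0.914, 84 genes at an unadjusted p under 0.05) and DESeq2 0. In that comparison the ribosomal protein list was higher with acetate, with a median of 0.84 over 48 genes, 0 called members and a camera adjusted p of 2.38e-05; the adjusted p was 0.464 with an estimated correlation. No other list passed camera between nitrate groups, with a lowest adjusted p of 0.0697 for cell division between 144 h and 48 h with acetate. With fry, cell division passed there (adjusted p = 0.00749), between donors at 144 h (0.0474) and in the interaction (0.0141). No other list passed fry between nitrate groups, and the ribosomal list had an adjusted p of 0.181 by fry between donors at 48 h. At 144 h edgeR called 0 between the donors (lowest adjusted p = 0.615, 133 genes), while DESeq2 called 9 genes higher with acetate and edgeR without the count filter called 12. The 9, chosen after their values were seen, were GSU0220, coxB, GSU0223, GSU0224, GSU0471, hcp, GSU3245, GSU3246 and GSU3247, with DESeq2 log2 fold changes of 2.94 for GSU0471 to 5.97 for GSU0220. Acetate 144 h replicate 2 carries a treatment label of hydrogen-nitrate 144 h, so whether these are donor differences depends on which label is right. That library had coxB at 7682, hcp at 4985 and GSU3247 at 4597 normalized CPM, against 2533, 928 and 557 in replicate 1. The interaction of donor and time gave 0 genes with edgeR (lowest adjusted p = 0.583, 109 genes at an unadjusted p under 0.05), 0 with DESeq2 and 9 with edgeR without the filter. In simulated counts for the 4 pairwise comparisons 73% to 80% of 16-fold changes and 18% to 30% of 4-fold changes were recovered, so most of the simulated 4-fold changes were missed. The simulations used the spread estimated from the labelled groups.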

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

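No explanation was tested for the values in this part. Of 60 values tested for a library far from the other nitrate libraries, 2 stood apart, and chance alone sets apart about 1 in 20. GSU1409 had 17.03 normalized CPM in acetate-nitrate 48 h replicate 2, against 0 to 5.99 in the other 7 nitrate libraries and 179.24 and 189.24 in the control libraries. rplT, which encodes a ribosomal protein, had 136.7 normalized CPM in acetate-nitrate 48 h replicate 1, against 0 to 35.68 in the other 7 and 270.17 and 299.73 in the control libraries.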

How the results depend on the processing

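Scaling to total or protein-coding counts, absent genes at 0, crossed numbers and all settings of the all-nitrate comparison were chosen after the result was seen. With only the 2 groups in the fit, hydrogen 48 h, hydrogen 144 h, acetate 48 h and acetate 144 h against the control gave 388, 504, 116 and 433 genes. Scaling to total counts gave 855, 546, 640 and 860, and 1159 for all nitrate libraries; scaling to protein-coding counts gave 409 at hydrogen 48 h, 286 at acetate 48 h and 514 at acetate 144 h. With acetate 144 h replicate 2 grouped by its treatment label, acetate 144 h gave 96. Without a count filter acetate against hydrogen at 144 h gave 12 and the interaction 9, and DESeq2 gave 9 in the first. Leaving out 1 library gave 7 to 141 genes at hydrogen 48 h, 0 to 15 at hydrogen 144 h, 0 to 167 at acetate 48 h, 9 to 157 at acetate 144 h and 105 to 542 for all nitrate libraries; where this leaves 1 library in a group, that library is assumed to vary like the other groups. Between nitrate groups it gave 0 each time. With total counts clpB, GSU1024 and trpD turned to −0.46, −0.40 and −0.25 in the all-nitrate comparison. For these changes the cause was not tested. RLE size factors, DESeq2 and genes absent from a table at 0 moved no total number of called genes against the control by over 1.5 times, but this does not hold for the counts of called list members. Of 104 such counts RLE moved 11, DESeq2 19, no filter 28, the fit of 2 groups 40, protein-coding counts 45 and total counts 52; the treatment label moved 14 and left 38, and leaving out a library moved 129 and left 287. The fold minimum of 2 moved nothing because every called change was larger, so it says nothing about stability. Of the calls of named genes, total counts ended 18, protein-coding counts 20, RLE size factors 4, no filter 9, the fit of 2 groups 6, the treatment label 23 and leaving out a library 401, while DESeq2 ended 0. In 64 cases a value past the threshold under neither setting changed sign. Of the list tests of each nitrate group against the control, an estimated correlation ended 9, all that had passed camera, and fry added 14. The replicate block gave 0 genes in the 4 comparisons between nitrate groups and in the interaction, as did the fit without it. Libraries with the same number did not deviate together (r across genes −0.29 to 0.10), so the numbers do not pair them; a block on crossed numbers gave 0 between times with either donor. Depth limits the lowest level that can be given: a floor of 3 counts was 9.22 to 20.4 CPM of the total.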

Other observations

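All tests in this part except that of library depth were chosen after the result was seen. Many genes called in the comparison of all 8 nitrate libraries with the control lay side by side, and these runs were looked for after the values were seen. At least 3 neighbouring loci were called the same way in 15 runs of higher and 27 runs of lower genes. No number of runs expected by chance is given, and read sharing between neighbouring genes was not tested. The run from GSU0221 to GSU3479, which holds the cytochrome oxidase gene coxB, had 5 loci and a median log2 fold change of 7.44, with nitrate libraries far apart: coxB ranged from 184 to 7682 normalized CPM and GSU0221 from 0 to 1264, below both controls in 1 library. GSU0966 to GSU0968 had 3 loci and a median of 5.35, and GSU1183 to GSU1185 3 loci and 4.46. The formate dehydrogenase gene fdnG, GSU0778 and hybB had a median of 3.34. GSU3409 to GSU3413, around the abundant GSU3410, had 4 loci and a median of 5.39. smpB, whose protein binds the transfer-messenger RNA, rose by 2.38 ± 0.52 (adjusted p = 0.00341 by edgeR, higher in 8 of 8 libraries), and with scaling to total counts its change was 0.58 and no longer called.

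Lower runs held genes of several cell functions. The 8 loci from GSU3529 to GSU3530 had a median of −4.06, the 7 loci from GSU0782 to GSU0788 with the hydrogenase genes hybA and hybB −2.31, and the 6 loci from GSU1465 to GSU1470 with mdh −2.67. The sigma factor gene rpoN lay in a run with lptB, lptA and lptC, genes of lipopolysaccharide transport, with a median of −3.09. A run of 7 loci from rpmD to rplE, mostly of ribosomal proteins, had a median of −2.46, and thrS, infC, rpmI, rplT and pheS one of −2.44.

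Each nitrate library was closest to a library of another labelled group, in 4 mutual pairs. Library depth and the share of structural RNA are argued against: after thinning to 1 protein-coding total the pairs differed by a chi-square per degree of freedom of at most 2.082, against at least 5.69 for the other 24 nitrate pairs. Batches that follow the replicate number are argued against too, since 0 of the 4 pairs join libraries with the same number. Labels exchanged between nitrate groups are a candidate explanation that stays open. The pairs differed by at most 2.882 over all genes, against 2.61 for the control pair and at least 16.04 for labelled pairs. In the order hydrogen 48 h, hydrogen 144 h, acetate 48 h, acetate 144 h, each replicate 1 paired with replicate 2 of the next group. The last replicate 1 paired with replicate 2 of the first group. Replicate 2 labels shifted by 1 group would give this order, but the labels alone cannot test it. Batches that the labels do not name, and cultures or libraries entered under 2 labels, stay open as well, and no biological explanation was tested.

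The RNAs ssrA and rnpB took a larger share of counts in every nitrate library, though transfer RNAs took a smaller one, and many genes were called. Deeper control libraries as the source of the falls were tested only in part. With the controls thinned to 93127 protein-coding counts, at least 77.3% of all 375 lower calls in each of 10 draws were still called. So were 82.4% of the 34 genes lower in all 4 comparisons. The thinned total includes GSU3410, which took 1.60% of control counts and 7.70% to 20.2% of nitrate counts. The thinned controls thus stayed deeper on other genes, and the test does not exclude depth as a source. The 267 lower calls with over 3 nitrate counts had a median log2 fold change of −2.87 before (quartiles −3.30 and −2.46) and −2.85 after (−3.33 and −2.47). Random thinning is not expected to move fold changes, so these medians do not bear on depth. Scaling as the source of the rises cannot be told apart from changes in the cells: 39.1% of the 46 genes higher in all 4 comparisons were still called higher with scaling to total counts, and no spike-in or cell count was used here to set the scale. A change in RNA content between growing cells and cells incubated with nitrate stays open, untested.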
